A study of Mus musculus with 12 samples.

How the data were processed

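RNA of mouse cardiac fibroblasts was measured by RNA sequencing in 12 libraries that the labels place in 4 groups of 3: vehicle and 6 µM MCB-613-10-1, each harvested after 4 h or 24 h. Per the labels' protocols, the cells were primary fibroblasts isolated from hearts of C57BL/6 mice and grown with serum, the vehicle was ethanol, and RNA was taken with a column kit. The labels do not say whether the replicates of a group were separate cultures or animals, so every p-value measures only the spread between these samples, which may be technical. The labels do not state whether the library kit marked strand.

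Per the submitters' processing notes, which name tools without their role or order, the authors' processing used HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 (version not given), with the genome build GRCm39 (mm39). The authors deposited, per the file headers, 1 comparison table per time point. Each held raw read counts per gene and library, the deposited count signal divided by 1 size factor per library, FPKM, and the authors' own log2 fold change with its p-value and adjusted p-value. Genes with a total under 2 counts over the 6 libraries of a time were not in these tables, which left 26240 genes at 4 h and 27020 at 24 h. The deposited FPKM values rest on library totals that differ from the plain sums of the counts. At 24 h these totals were 1.10 to 1.11 times the sums in vehicle and 0.954 to 0.981 times in treated libraries, so the FPKM values carry a scaling between groups. A separate FPKM table per time held the same FPKM columns over all annotated genes. Each time point was normalized separately by the authors, so tests across times started from the raw counts, except the alternative with limma-trend on FPKM values. In the 24 h table the names of the group means carry a prefix that those at 4 h lack and that the labels do not explain, so whether the 24 h and 4 h libraries differ in more than time is not known. In the authors' deposited table, adjusted p was exactly 1 for 12718 genes at 4 h and for 4716 genes at 24 h.

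The raw counts were tested with the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3), after the filter of low counts that edgeR applies by default and TMM scaling, with robust dispersion estimates. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. The 4 h and the 24 h response were each fitted on their own 6 libraries without a replicate block. The difference between the responses was fitted on all 12 libraries as an interaction, with a gene absent from 1 of the tables entered as 0 counts there. Values per group are CPM after TMM scaling within a time, as mean ± SD over 3 libraries, and a log2 fold change is treated minus vehicle with its standard error (SE). Symbols, identifiers and coordinates are those of the deposited tables, which describe whole genes on GRCm39. The reference genome at hand was of another build, and none of its coordinates were used. Its transcript sequences gave GC content by gene identifier for 98.8% of the tested genes at 4 h and 98.7% at 24 h.

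The 23 gene lists were fixed before the data were examined, as were the tests, the other settings tried and the rule for naming genes. The lists cover NRF2 targets, ATF4 and the integrated stress response, ER chaperones and ATF6/XBP1 targets, the heat shock response, fibrillar collagens and matrix, the myofibroblast and TGF-beta response, inflammatory cytokines and chemokines, the interferon response, the cell cycle, immediate early genes and MAPK feedback, cholesterol biosynthesis, p53 targets, the proteasome, metallothioneins and metal response, steroid receptor coactivators, oxidative phosphorylation, fibroblast identity, and markers of cardiomyocytes, endothelium, macrophages and leukocytes, pericytes and smooth muscle, epicardium and mesothelium, and Schwann cells. Each list was tested against all other genes with camera at a preset correlation of 0.01 between genes, on log2 CPM with a prior count of 2, two-sided and adjusted over the 23 lists. Camera with an estimated correlation and fry were alternatives. Fry asks whether the genes of a list move, on balance, one way, and compares them with no other genes. Members were also counted with p-values adjusted over the list alone.

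Genes were named by a fixed rule. It took the 5 protein-coding genes with the largest rise and the 5 with the largest fall at each time, among called genes whose treated libraries all lay on one side of the vehicle libraries and whose higher group had a mean FPKM of at least 1. It added the 2 called members of each list with the largest change at each time and the same FPKM minimum, 10 genes named whatever their result (Nfe2l2, Keap1, Nqo1, Hmox1, Ncoa1, Ncoa2, Ncoa3, Col1a1, Acta2, Postn), and the 3 largest positive and 3 largest negative differences between the times. Other members that are named as examples or exceptions of a list or gene family were chosen after their values were seen. Not every gene that the rule picks is reported.

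Libraries held from 26869195 to 31596784 counts at 4 h and from 25016754 to 34877090 at 24 h. The steps were tested on simulated counts drawn from the real means and library sizes, with up to 50 genes changed at each fold. Of genes changed 1.5-fold, 36.7% were recovered at 4 h, 63.3% at 24 h and 24.0% in the test of the difference. The share was 70.0%, 81.2% and 56.0% at a fold of 2, and 94.0%, 96.0% and 86.0% at a fold of 4. False calls made up 8.04%, 13.2% and 3.30% of the calls. A raised gene list was recovered each time, and 0 unchanged lists were called. The simulated genes varied independently of each other, so this does not show how often correlated lists would be falsely called. In the real data the estimated correlation within a list reached 0.87 (interferon at 4 h).

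Alternatives were the replicate number as a block, DESeq2 1.42.0, median-ratio (RLE) factors, library totals alone, no filter beyond a nonzero count, a mean FPKM of at least 1, limma-trend on log2(FPKM + 0.5), a minimum absolute log2 fold change of 1, all 12 libraries in the fits of each time, and each library left out in turn. Fits without ribosomal RNA genes and without the 100 most abundant genes were added after seeing the data. Pseudocounts of 0.1 and 1 and other scalings of FPKM were planned only for the case that no counts were given, and were not run. Other splits of the libraries were counted over all 10 splits at each time and over 100 drawn for the difference. Groups of 3 are too small for a test of outlying libraries. Floors for genes at 0 counts (3 counts over the group) and 95% intervals of ratios (exact binomial) cover counting error only.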

Results

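The series measured how cultured mouse cardiac fibroblasts, the matrix-producing cells of the heart, responded to MCB-613-10-1, a derivative of the compound MCB-613 that is described in the series as acting against fibrosis. Its title connects steroid receptor coactivators with NRF2, the transcription factor of the oxidative stress response. Cells received vehicle or 6 µM MCB-613-10-1 for 4 h or 24 h, with 3 libraries in each of the 4 groups. Libraries held from 26869195 to 31596784 counts at 4 h and from 25016754 to 34877090 at 24 h. Across genes, log2 CPM correlated between libraries of a group with r from 0.986 to 0.993 at 4 h and from 0.990 to 0.992 at 24 h. Between treated and vehicle libraries r ran from 0.979 to 0.989 at 4 h and from 0.904 to 0.920 at 24 h.

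After 4 h, the largest rises by the naming rule were those of genes of the NRF2 and heat shock responses. Hmox1 (heme oxygenase 1, ENSMUSG00000005413, GRCm39 chromosome 8, 75820249 to 75827217) went from 1277 ± 165 to 6802 ± 299 CPM (SD, n = 3 each), a log2 fold change of 2.41 (SE 0.10, edgeR adjusted p = 1.13e-07). Srxn1 (sulfiredoxin, ENSMUSG00000032802, chromosome 2, 151947436 to 151953296) rose 5.73-fold and Osgin1 (ENSMUSG00000074063, chromosome 8, 120160863 to 120172995) 7.57-fold. Of the 36 NRF2 targets measured, 26 rose and 0 fell. The counts were 30 and 0 when adjusted over the list alone, and the median log2 fold change was 0.65 (camera adjusted p = 3.1e-31, and adjusted p = 0.0246 with an estimated correlation). Gclm and Gclc, the subunits of the enzyme that starts glutathione synthesis, were among them, with log2 fold changes of 1.88 and 1.23. Nqo1, a quinone reductase (ENSMUSG00000003849, chromosome 8, 108114857 to 108129838), rose less, from 109 ± 13.6 to 150 ± 17.4 CPM (log2 fold change 0.47, edgeR adjusted p = 0.0273). Keap1, which targets the NRF2 protein for degradation, rose by 0.43 (adjusted p = 0.0339), and Nfe2l2, which encodes NRF2, was not called (0.12, adjusted p = 0.472). The call of Nqo1 ended without vehicle replicate 2 or 3 or treated replicate 1 or 3 (adjusted p = 0.0863, 0.0998, 0.109 and 0.146), and with library totals or FPKM values (0.0559 and 0.0656). That of Keap1 ended without vehicle replicate 3 or treated replicate 2 or 3 (0.0591, 0.173 and 0.144), and with library totals or FPKM values (0.0531 and 0.0693).

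Heat shock genes rose together at 4 h. Of 23 members measured, 18 rose and 0 fell, and 20 and 0 when adjusted over the list alone. The heat shock median was 0.80 (camera adjusted p = 3.0e-30, and adjusted p = 0.0183 with an estimated correlation). The inducible chaperone genes Hspa1a (ENSMUSG00000091971, chromosome 17, 35188166 to 35191132) and Hspa1b (ENSMUSG00000090877, chromosome 17, 35175412 to 35178214) rose 43.2-fold and 29.6-fold. They are near-identical copies, so how their reads divide between them is uncertain. Hsph1 and Dnajb1 followed with log2 fold changes of 2.15 and 1.80. In the list of ATF4 and the integrated stress response, 13 of 31 members rose and 0 fell, and 24 and 0 when adjusted over the list alone. Its median was 0.36 (camera adjusted p = 5.4e-19, and adjusted p = 0.0246 with an estimated correlation). Chac1, which degrades glutathione, rose by 1.73 (SE 0.11) and Gdf15, a secreted stress cytokine, by 1.61 (SE 0.13). Of 26 ER chaperones and ATF6/XBP1 targets, 1 rose, Herpud1 (log2 fold change 0.60, edgeR adjusted p = 0.00193), and 0 fell, 1 and 0 when adjusted over the list alone (median 0.07, camera adjusted p = 0.205).

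Proteasome and p53 target genes rose in part at 4 h. Of 33 proteasome genes, 6 rose and 0 fell, likewise 6 and 0 when adjusted over the list alone, led by Adrm1 (log2 fold change 0.71, edgeR adjusted p = 0.00999) and Psmd11 (0.66, adjusted p = 0.000345). The list had a median of 0.16 (camera adjusted p = 1.2e-05, but adjusted p = 0.367 with an estimated correlation and 0.0658 with fry). The call of Adrm1 ended without treated replicate 2 (adjusted p = 0.0537). Of 24 p53 targets, 6 rose and 0 fell, 7 and 2 when adjusted over the list alone (median 0.12, camera adjusted p = 0.0075, but adjusted p = 0.329 with an estimated correlation). Gadd45a, a stress-inducible gene of growth arrest, rose by 1.26 (SE 0.18) and Pmaip1, a pro-apoptotic BCL2 family member, by 0.66 (SE 0.11). Of 7 genes of metal response, Slc40a1, the iron exporter, rose by 1.71 (edgeR adjusted p = 0.000271) and Mtf1 by 0.31 (adjusted p = 0.0462). Here 3 rose and 2 fell when adjusted over the list alone, and the list was not called (median 0.23, camera adjusted p = 0.302). The call of Mtf1 ended without vehicle replicate 2 or 3 (0.0935 and 0.16) or without treated replicate 1, 2 or 3 (0.106, 0.176 and 0.161), and with library totals or FPKM values (0.0916 and 0.0627). Without vehicle replicate 1 the metal list was called, at 0.0475.

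Some genes of the cell cycle, of cytokines and of cholesterol synthesis fell at 4 h. Of 38 cell cycle genes, 19 fell and 0 rose, and 26 and 0 when adjusted over the list alone. The cell cycle median was -0.46 (camera adjusted p = 7.4e-14, but adjusted p = 0.32 with an estimated correlation). Ccna2 (cyclin A2, ENSMUSG00000027715, chromosome 3, 36619014 to 36626299) went from 40.8 ± 4.86 to 20.8 ± 3.72 CPM (SD, n = 3 each), and Plk1, a mitotic kinase, fell by 0.95 on the log2 scale (SE 0.17). Of 30 inflammatory genes, 8 fell and 0 rose, 11 and 0 when adjusted over the list alone (median -0.35, camera adjusted p = 1.5e-06, but adjusted p = 0.116 with an estimated correlation). Among them, Has2, a hyaluronan synthase (ENSMUSG00000022367, chromosome 15, 56529023 to 56557935), was 5.00-fold lower and Il6, an inflammatory cytokine, had a log2 fold change of -1.39 (SE 0.18). Of 25 cholesterol synthesis genes, 8 fell and 0 rose, 10 and 0 when adjusted over the list alone (median -0.32, camera adjusted p = 5.8e-06, but adjusted p = 0.346 with an estimated correlation). Idi1 stood at -0.98 and Msmo1 at -0.79. By the naming rule, the other largest falls were those of Tnfsf15, a cytokine of the TNF family (-2.49, SE 0.13), Mycn, a transcription factor of the MYC family (-2.40, SE 0.17), Pif1, a DNA helicase (-1.69, SE 0.22), and Lbh (-1.68, SE 0.11).

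Most fibrosis genes were not called at 4 h. Of 40 collagen and matrix genes 2 fell, Thbs1 (thrombospondin 1, -0.65, edgeR adjusted p = 0.00126) and Col8a1 (-0.39, adjusted p = 0.0201), and 0 rose, also when adjusted over the list alone (median 0.02, camera adjusted p = 0.822; the median is negative when scaled by library totals). Col1a1, the main collagen I chain (ENSMUSG00000001506, chromosome 11, 94827050 to 94843868), had a log2 fold change of 0.18 (adjusted p = 0.326). Acta2, smooth muscle actin (ENSMUSG00000035783, chromosome 19, 34218490 to 34232990), stood at -0.14 (0.413) and Postn, periostin (ENSMUSG00000027750, chromosome 3, 54268530 to 54298458), at -0.14 (0.348). Of 33 genes of the myofibroblast and TGF-beta response, 6 fell and 0 rose, 8 and 0 when adjusted over the list alone, led by the transcription factor Meox1 (-1.66, SE 0.12) and by Id3, an inhibitor of basic helix-loop-helix factors (-0.91, SE 0.16). The list's call (median -0.08, camera adjusted p = 0.0093) was lost with an estimated correlation (adjusted p = 0.538), with fry (0.131), without vehicle replicate 3 (0.116) and without treated replicate 1 (0.0705). Of 18 fibroblast identity genes, Tcf21 (-1.10, edgeR adjusted p = 0.0113) and Tbx20 (-0.96, adjusted p = 0.00235) fell and Gata4 rose. When adjusted over the list alone 2 rose and 5 fell, and the list was not called (median -0.08, camera adjusted p = 0.277). The call of Col8a1 ended with FPKM values (0.0537), without vehicle replicate 3 (0.0916) and without treated replicate 1, 2 or 3 (0.0851, 0.0676 and 0.0986). Those of Tcf21 and Tbx20 ended without vehicle replicate 1 (0.0664 and 0.0511), and that of Tcf21 also without a filter (0.0712).

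The other lists were not called at 4 h in the main test, though some of their members were. In the immediate early and MAPK feedback list, 3 of 33 members rose and 6 fell, 5 and 9 when adjusted over the list alone (median -0.02, camera adjusted p = 0.416). The phosphatase gene Dusp6 stood at -1.03 and Egr3 at -0.63. Of 14 steroid receptor coactivators and partners 1 rose and 2 fell, 2 and 3 when adjusted over the list alone (median 0.01, mean -0.05, camera adjusted p = 0.834). The glucocorticoid receptor gene Nr3c1 stood at -0.41 (edgeR adjusted p = 0.0102). Ncoa1, Ncoa2 and Ncoa3 were not called (0.14, -0.01 and 0.21, adjusted p = 0.382, 0.967 and 0.153), although Ncoa3 passed with all 12 libraries in the fit (0.0421). The call of Nr3c1 ended without treated replicate 2 or 3 (0.0524 and 0.0849). None of the 29 interferon genes and none of the 35 oxidative phosphorylation genes was called, also when adjusted over the list alone (edgeR; medians 0.03 and -0.03, camera adjusted p = 0.834 and 0.822). The interferon list's median and mean (0.05) had the opposite sign to its test. It was called upward without treated replicate 2 (0.000134) and downward without treated replicate 3 (9.9e-05), the libraries with the lowest and the highest level of these genes in their group. The oxidative phosphorylation list was called without vehicle replicate 1, at 0.0248. Of the markers of other cell types, Lyz2, a lysozyme of macrophages, fell among 15 leukocyte genes (-0.58, edgeR adjusted p = 0.0214), likewise 1 when adjusted over the list alone. The call of Lyz2 ended with FPKM values (0.0614), without vehicle replicate 3 (0.0682) and without treated replicate 2 or 3 (0.0715 and 0.0813). No other marker of leukocytes, cardiomyocytes (5 measured), endothelium (12), pericytes and smooth muscle (7), epicardium and mesothelium (7) or Schwann cells (3) was called, except 1 cardiomyocyte gene that rose when adjusted over its list alone. The medians of these 6 lists ran from -0.10 to 0.27 (camera adjusted p from 0.629 to 0.972).

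In total, edgeR called 1098 of 15336 genes at 4 h, 529 higher and 569 lower, of which 200 changed by at least 1 log2 unit (119 higher, 81 lower). The authors' deposited table called 1419 genes at 4 h, and 1056 were shared. The count without 1 library was 1760 without vehicle replicate 1, which lay apart from the other vehicle libraries, and 672, 634, 476 and 443 without vehicle replicate 3 or treated replicate 1, 2 or 3. With all libraries of 4 h kept, it was 701 with limma-trend on FPKM values, 1953 with the replicate number as a block and 2198 with all 12 libraries in the fit. The share of higher genes was 48.2%, and 34.5% when scaled by library totals alone.

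**Figure D1:**
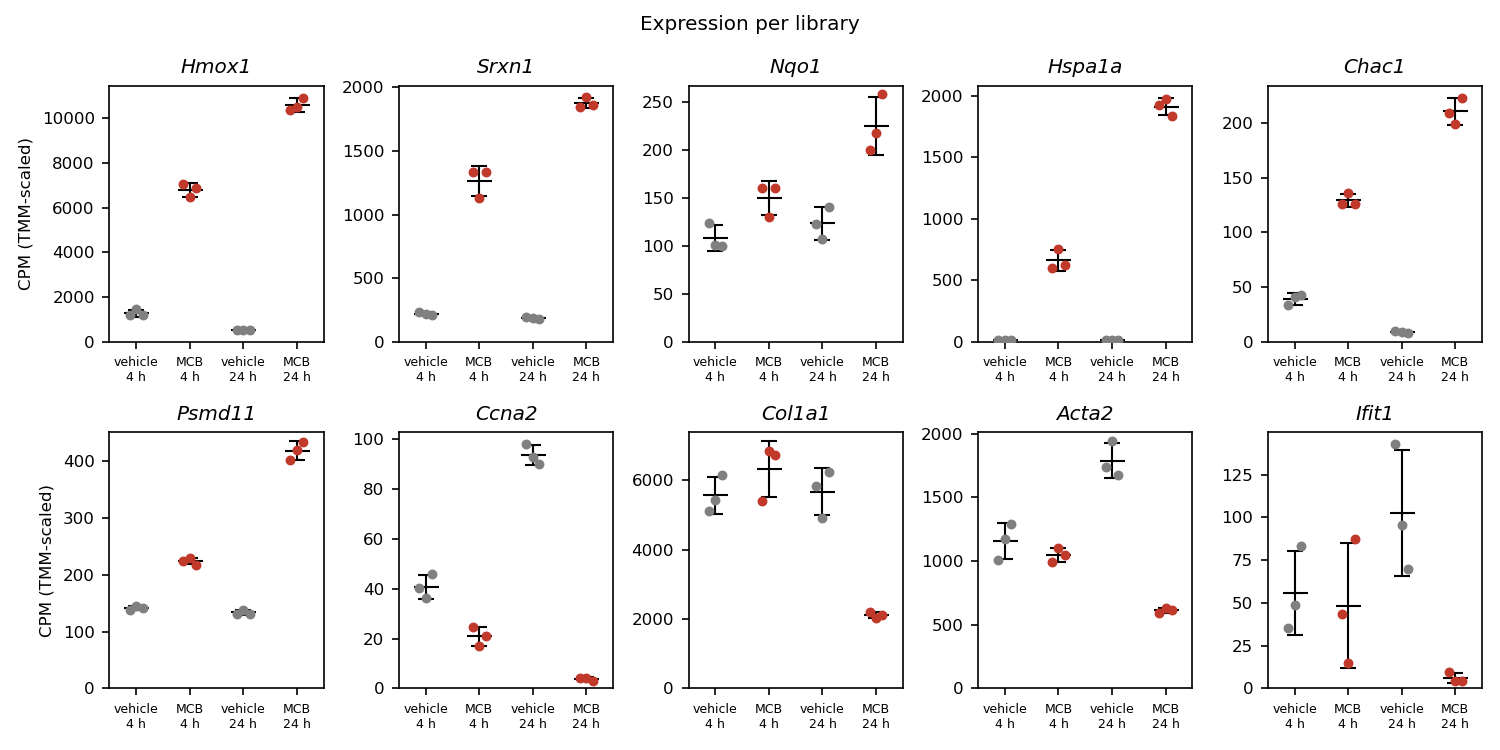
Normalized expression (CPM after TMM scaling, linear axes from 0) of 10 genes in each library at 4 h and 24 h, with vehicle in gray, MCB-613-10-1 (MCB) in red, and black bars for the mean ± SD of 3 libraries. Hmox1 stood at 1277 and 6802 CPM in vehicle and treated cells at 4 h and at 521 and 10601 CPM at 24 h, whereas Col1a1 and Acta2 were called as lower at 24 h only and the values of Ifit1 spread widely within groups.

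After 24 h the same 3 stress responses stood higher. Hmox1 went from 521 ± 8.03 to 10601 ± 295 CPM (SD, n = 3 each), 20.4-fold, Srxn1 rose 10.2-fold and Osgin1 17.5-fold. Nqo1 rose 1.83-fold (log2 fold change 0.87, edgeR adjusted p = 0.00429) and Keap1 1.44-fold. Nfe2l2 rose by 0.32 on the log2 scale (adjusted p = 1.2e-06). Of 37 NRF2 targets, 32 rose and 3 fell, likewise 32 and 3 when adjusted over the list alone (median 1.34, camera adjusted p = 6.7e-11, but adjusted p = 0.116 with an estimated correlation). Gsta2, a glutathione transferase, reached 4.44 (SE 0.44), and the members that fell were Ugdh (-0.51), G6pdx (-0.54) and Ephx1 (-0.58). Of 23 heat shock genes, 22 rose and Fkbp4 fell (-0.25), with the same counts when adjusted over the list alone (median 1.98, camera adjusted p = 5.3e-13, but adjusted p = 0.279 with an estimated correlation). Hspa1a rose 164-fold and Hspa1b 96.8-fold. In the ATF4 list 29 of 31 rose and Pycr1 fell (-0.33), with the same counts when adjusted over the list alone (median 1.49, camera adjusted p = 2.0e-12, but adjusted p = 0.215 with an estimated correlation). Atf3, a stress-induced transcription factor, stood at 5.09 (SE 0.06) and Chac1 at 4.52 (SE 0.07).

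All genes of the proteasome list rose at 24 h: 33 of 33 measured were higher, also when adjusted over the list alone, by log2 fold changes of 0.78 to 2.08 (median 1.47, camera adjusted p = 5.7e-16, but adjusted p = 0.329 with an estimated correlation). By symbol, 10 Psmb genes were tested, some of them outside the list, and 7 rose and 3 fell. Psmb3 rose by 2.08 (SE 0.05) and Adrm1 by 1.89 (SE 0.05). ER chaperones and ATF6/XBP1 targets moved both ways, 17 of 26 higher and 7 lower, with the same counts when adjusted over the list alone (median 0.30, camera adjusted p = 0.014, but adjusted p = 0.39 with an estimated correlation). Hspa5, the main ER chaperone, rose by 2.41 (SE 0.05) and Herpud1 by 1.96, whereas Sec61b (-0.67), Manf (-0.31) and Xbp1 (-0.24) fell. Of 24 p53 targets 15 rose and 7 fell, with the same counts when adjusted over the list alone (median 0.39, camera adjusted p = 0.014, but adjusted p = 0.329 with an estimated correlation). Gadd45a stood at 3.21, Pmaip1 at 1.85 and Fas at -1.57. In the immediate early and MAPK feedback list 21 of 33 rose and 8 fell, with the same counts when adjusted over the list alone (median 0.55, camera adjusted p = 0.014, but adjusted p = 0.39 with an estimated correlation). Areg, an EGF receptor ligand, rose by 2.99 (SE 0.39) and Egr1 by 2.66 (SE 0.07). Of 7 metal response genes 5 rose and 2 fell, with the same counts when adjusted over the list alone (median 0.82, camera adjusted p = 0.183). The metallothionein genes Mt2 and Mt1 rose by 3.51 and 2.35.

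Matrix and myofibroblast genes fell at 24 h. Col1a1 went from 5671 ± 682 to 2124 ± 87.7 CPM (SD, n = 3 each), 2.67-fold lower, Acta2 from 1788 ± 138 to 612 ± 20.3 CPM, 2.92-fold lower, and Postn fell by 0.59 on the log2 scale. Of 40 collagen and matrix genes, 33 fell and Mfap5 rose (0.52), with the same counts when adjusted over the list alone (median -1.25, camera adjusted p = 5.0e-09, but adjusted p = 0.329 with an estimated correlation). Col11a1 stood at -3.02 (SE 0.09) and Aspn at -2.89 (SE 0.66). Of 33 myofibroblast and TGF-beta genes, 23 fell and 4 rose, 23 and 5 when adjusted over the list alone (median -0.77, camera adjusted p = 6.2e-05, but adjusted p = 0.179 with an estimated correlation). Tgfbi fell by 4.30 on the log2 scale and Lmod1 by 3.26, while the members that rose were Smad7 (1.19) and Skil (0.66), inhibitors of TGF-beta signaling, the receptor gene Tgfbr1 (0.30) and Ccn1 (0.19). Acta2 and Lmod1 are also genes of smooth muscle, whose markers, with those of pericytes, had a median of -1.32. Of 18 fibroblast identity genes 13 fell and 2 rose, with the same counts when adjusted over the list alone (median -1.15, camera adjusted p = 0.0042, but adjusted p = 0.39 with an estimated correlation). Mgp stood at -3.17, Medag at -2.92, Tbx20 at -2.70 and Ddr2 at 0.62.

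Cell cycle and interferon genes fell furthest at 24 h. Of 38 cell cycle genes 37 fell, also when adjusted over the list alone, and Mcm2 was not called (median -2.75, camera adjusted p = 8.2e-17, but adjusted p = 0.215 with an estimated correlation). Cenpf, a centromere protein gene, had a log2 fold change of -4.75 (SE 0.13) and Ccna2 of -4.62 (SE 0.10), from 93.7 ± 3.92 to 3.76 ± 0.848 CPM. Of 29 interferon genes 28 fell and Ifi27 rose (0.24), with the same counts when adjusted over the list alone (median -2.23, camera adjusted p = 1.7e-09, but adjusted p = 0.329 with an estimated correlation). Ifit1 (ENSMUSG00000034459, chromosome 19, 34618271 to 34627409) fell by 4.12 and Ifit3b by 4.08 on the log2 scale. Of 26 inflammatory genes 17 fell and 3 rose, with the same counts when adjusted over the list alone (median -1.22, camera adjusted p = 0.0028, but adjusted p = 0.329 with an estimated correlation). Has2 was 31.1-fold lower and Cxcl10, an interferon-induced chemokine, stood at -3.97, while Ptgs2, the inducible cyclooxygenase, rose (1.80). Markers of leukocytes moved with these groups: 11 of 13 fell, among them the complement genes C1qb (-3.32) and C1qc (-2.67), and Cd14 (1.09) and Csf1r (0.22) rose, with the same counts when adjusted over the list alone (median -1.48, camera adjusted p = 0.0063, but adjusted p = 0.39 with an estimated correlation). Of 25 cholesterol synthesis genes 19 fell and 3 rose, 20 and 3 when adjusted over the list alone (median -1.12, camera adjusted p = 0.00041, but adjusted p = 0.329 with an estimated correlation). Idi1 stood at -2.12 and Mvk at -2.05, and Sc5d (1.06) and Msmo1 (0.22) were among those that rose. The rise of Msmo1 ended with library totals (adjusted p = 0.767), with all 12 libraries in the fit (0.0634) and without vehicle replicate 2 (0.0629).

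Most of the remaining lists moved both ways at 24 h, while the called markers of pericytes and smooth muscle and of Schwann cells all fell. Among 13 steroid receptor coactivators and partners 6 rose and 5 fell, with the same counts when adjusted over the list alone (median -0.04, mean 0.05, camera adjusted p = 0.872). Ncoa3 rose by 0.56 (SE 0.06) and Ncoa1 by 0.24 (SE 0.07), Ncoa2 fell by 0.46 (SE 0.06), Nr3c1 by 0.50 and the methyltransferase gene Prmt1 by 0.98. The rise of Ncoa1 ended when scaled by library totals (edgeR adjusted p = 0.531). Of 35 oxidative phosphorylation genes 9 rose and 14 fell, 8 and 12 when adjusted over the list alone (median 0.01, or -0.18 when scaled by library totals, with a test of the opposite sign to the median, camera adjusted p = 0.885). The complex I genes Ndufb10 and Ndufa1 stood at -0.90 and 0.82. Of the 12 endothelial markers 5 rose, Fabp4 among them (1.23), and 7 fell, Egfl7 among them (-1.22), with the same counts when adjusted over the list alone (median -0.63, camera adjusted p = 0.691). Of 6 pericyte and smooth muscle markers 4 fell, Mcam (-2.27) and Notch3 (-2.17) furthest, and 0 rose, also when adjusted over the list alone (median -1.32, camera adjusted p = 0.0488, but adjusted p = 0.329 with an estimated correlation). The pericyte call ended without vehicle replicate 2 or 3 or treated replicate 1 (0.0509, 0.0527 and 0.0517). Of 6 epicardial and mesothelial markers 3 fell, Lrrn4 (-1.99) and Upk3b (-1.27) among them, and Krt19 rose (1.17), 2 and 1 when adjusted over the list alone (median -0.25, camera adjusted p = 0.577). Of 3 Schwann cell markers 2 fell, Cnp at -1.83, also when adjusted over the list alone (median -1.11, camera adjusted p = 0.267). Of 2 cardiomyocyte markers Nppb, a natriuretic peptide gene (ENSMUSG00000029019, chromosome 4, 148070245 to 148071662), rose from 0.339 ± 0.238 to 19.9 ± 3.40 CPM (SD, n = 3 each), and Tnnt2 fell (-1.44), also when adjusted over the list alone (median 2.18, camera adjusted p = 0.872).

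Several of the largest rises at 24 h were in genes with almost no counts in the 24 h vehicle libraries. Krtap4-16, a keratin-associated protein gene (ENSMUSG00000046474, chromosome 11, 99741481 to 99742434), had 0 counts in the vehicle libraries and 351 in the treated ones, at least 152-fold higher. Trim54, a muscle RING finger gene, had 0 and 143 counts, at least 62.1-fold higher, and Fgf21, a stress-induced hormone of the FGF family, had 0 and 110, at least 47.8-fold higher. Mt3, a metallothionein gene, had 1 and 489 counts, a ratio of 637 (95% exact binomial interval of the counts 114 to 25200), and Sstr5, a somatostatin receptor gene, had 1 and 310, a ratio of 404 (71.9 to 16000). These folds were taken against the 24 h vehicle libraries. For Krtap4-16, Fgf21 and Sstr5 they hold against those libraries alone, since the 4 h vehicle libraries held 108, 20 and 14 counts. Krtap4-16 stood at 1.22 CPM there, against 4.47 CPM in treated cells at 24 h. Of Mt3 and Trim54 the 4 h vehicle libraries held 3 and 2 counts. By the naming rule, with its limits on FPKM and separation, the largest falls were those of Olfml1 (-6.31, SE 0.61, ENSMUSG00000051041, chromosome 7, 107166653 to 107190301), Heyl, a Notch target (-5.53, SE 0.74), Dkk2, a secreted Wnt modulator (-5.33, SE 0.32), Iigp1, an interferon-inducible GTPase (-5.28, SE 0.72), and Pdlim3, a PDZ and LIM domain protein of muscle (-5.19, SE 0.67).

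In total, edgeR called 11628 of 15575 genes at 24 h, 5713 higher and 5915 lower, of which 4908 changed by at least 1 log2 unit (2112 higher, 2796 lower). The authors' deposited table called 11330 genes at 24 h, and 10771 were shared. The share of higher genes was 49.1%, and 39.0% when scaled by library totals alone, which shifted the median of all genes by -0.19 on the log2 scale, and changes at 24 h are relative to this choice.

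**Figure D2:**
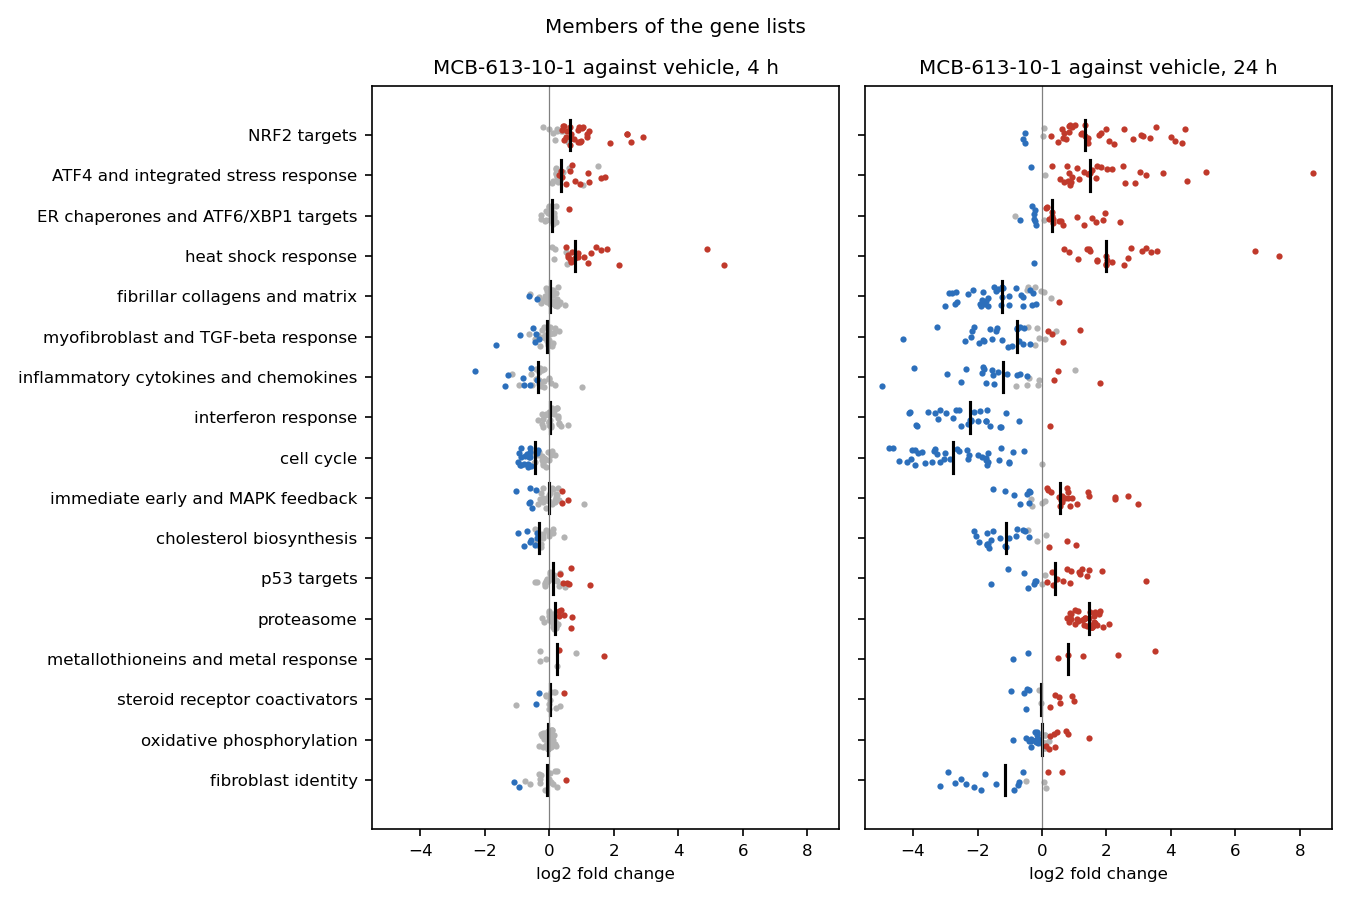
Log2 fold changes (treated minus vehicle, x axes) of the members of 17 gene lists (rows) at 4 h (left) and 24 h (right), with 1 point per gene in red (called higher), blue (called lower) or gray (not called), and a black bar at the list's median. All 33 proteasome genes lay on the higher side at 24 h and 37 of 38 cell cycle genes were called lower, whereas the interferon list had no called member at 4 h; the ATF4 list's rightmost point, Fgf21, had 0 vehicle counts, so its position depends on the prior count.

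The test of the difference asked which responses changed between 4 h and 24 h. The rise was larger at 24 h for Hmox1 by 1.94 on the log2 scale (SE 0.11, edgeR adjusted p = 1.4e-10) and for Atf3 by 4.46, and the fall of Ccna2 was larger (difference -3.65). Such a difference also holds any change in the vehicle level. In vehicle, Hmox1 stood at 1277 CPM at 4 h and 521 CPM at 24 h, each scaled within its time. Col1a1 and Acta2, not called at 4 h, differed by -1.59 and -1.40. Of the lists, the heat shock (median difference 1.23), proteasome (1.26), ATF4 (1.08) and NRF2 (0.41) lists differed upward, and the interferon (-2.41), cell cycle (-2.23) and matrix (-1.35) lists downward (camera adjusted p from 3.9e-22 to 2.6e-05, but adjusted p from 0.065 to 0.30 with an estimated correlation). Between the vehicle libraries, 24 h minus 4 h, medians had the opposite sign to these differences for ATF4 (-0.53), the cell cycle (1.02) and interferon (1.34). They had the same sign for NRF2 (0.25), heat shock (0.16), the proteasome (0.28) and matrix (-0.05). Of the 33 proteasome genes 33 differed upward, of 38 cell cycle genes 37 and of 40 matrix genes 35 downward, with the same counts when adjusted over the list alone. The largest differences by the naming rule were those of Krtap4-16, Trim54 and Prr9 upward, genes with 0, 0 and 4 counts in the 24 h vehicle libraries, and those of Gas1 (-5.64), Olfml1 (-5.25) and Pdlim3 (-5.17) downward. Olfml1 lost the call without treated 4 h replicate 1 (-3.92, adjusted p = 0.0826), and Trim54 without vehicle 4 h replicate 2 (adjusted p = 0.99985). Responses of Nfe2l2, Keap1, Nqo1, Ncoa1, Tnfsf15, Mycn, Nr3c1, Tcf21, Egr3 and Ndufa1 were not shown to differ (adjusted p from 0.052 to 0.518). In total 8796 of 16341 genes differed (4363 upward, 4433 downward), 3838 of them by at least 1 log2 unit. The share of upward differences was 49.6%, and 40.0% with library totals, a shift of -0.14 of the median of all genes.

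Genes called at 4 h mostly kept their direction at 24 h. Of 14779 genes tested at both times 1031 were called at both, and 480 were higher at both, including Hmox1, Hspa1a and Chac1, where independent lists would share 193. Another 508 were lower at both, including Has2, Il6 and Tnfsf15, against 220 for independent lists. Only 18 went from higher to lower and 25 from lower to higher, Msmo1 among the latter, against 204 and 209. Log2 fold changes correlated across genes with r = 0.507 (Spearman's rho 0.454), though genes are not independent replicates, and the times share no vehicle libraries. Of the 168 genes called at both times with at least 1 log2 unit, 166 kept their direction.

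**Figure D3:**
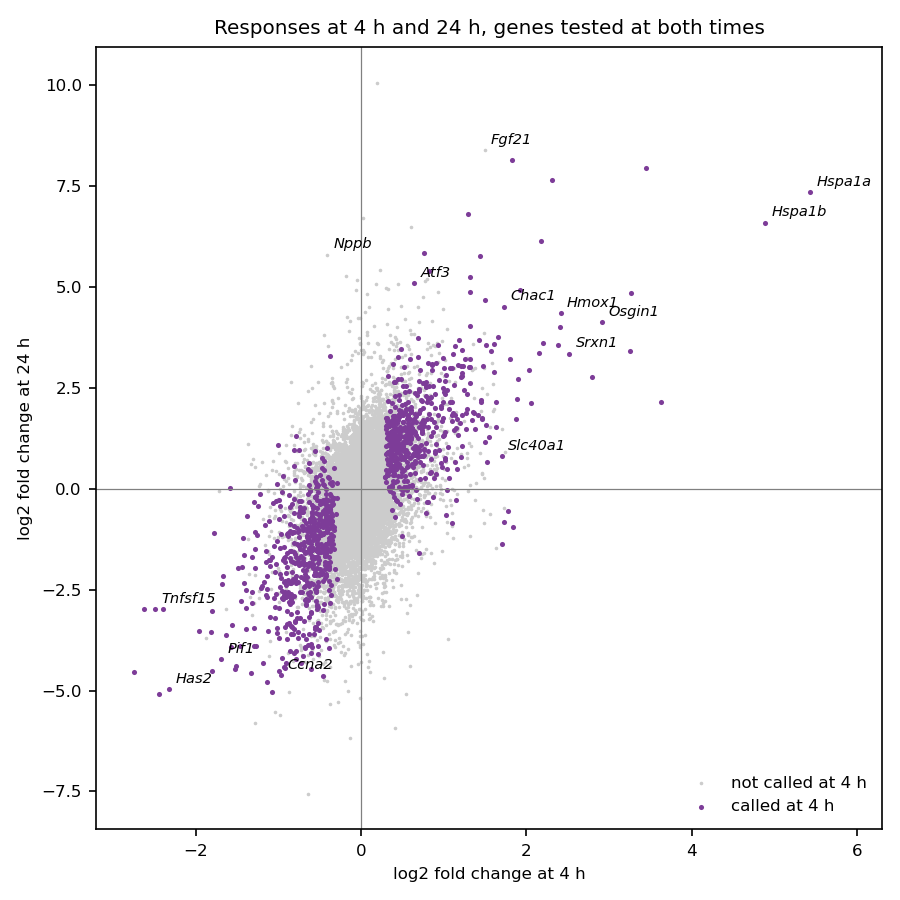
Log2 fold change at 24 h (y axis) against that at 4 h (x axis) for the 14779 genes tested at both times, with genes called at 4 h in purple and all others in gray. Hspa1a and Hspa1b lie at the upper right and Has2 at the lower left, and 988 of the 1031 genes called at both times kept their direction.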

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

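The tests of culture handling, of the interferon genes and of vehicle 4 h replicate 1 were chosen after the result was seen, and the splits of the libraries and the tests of spread and of length and GC content before it.

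The response of the genes below and of 15 gene lists differed between the times by a test of the difference itself (edgeR interaction for genes, camera for lists), given as log2 difference, 24 h minus 4 h. Positive differences for stress genes were Hspa1a 1.93, Hspa1b 1.71, Osgin1 1.22, Srxn1 0.84, Hmox1 1.94, Gsta2 3.10, Chac1 2.79, Gdf15 1.28, Atf3 4.46, Herpud1 1.36, Hspa5 2.26, Gadd45a 1.96, Pmaip1 1.20, Adrm1 1.19, Psmd11 0.99, Psmb3 1.81, Mt1 2.13, Mt2 2.67 and Mtf1 0.95. Other positive differences were Areg 2.73, Egr1 2.26, Dusp6 0.73, Msmo1 1.02, Ncoa3 0.36, Nppb 6.23, Fabp4 1.37 and Prr9 7.17. Krtap4-16 (9.86), Trim54 (7.55), Fgf21 (6.88), Mt3 (6.43) and Sstr5 (6.32) had 0 or 1 counts in the 24 h vehicle libraries, so that these fitted values depend on the prior count.

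Negative differences for matrix, myofibroblast and fibroblast genes were Col1a1 -1.59, Acta2 -1.40, Postn -0.45, Col11a1 -3.03, Col8a1 -1.52, Thbs1 -0.38, Aspn -2.30, Tgfbi -4.28, Lmod1 -2.63, Meox1 -0.49, Id3 -1.48, Mgp -3.14, Medag -2.15 and Tbx20 -1.74. Those for cell cycle, cytokine and interferon genes were Ccna2 -3.65, Plk1 -3.23, Cenpf -4.30, Pif1 -2.53, Has2 -2.63, Il6 -1.56, Cxcl10 -3.80, Ifit1 -3.91, Ifit3b -3.88 and Iigp1 -5.00. Markers of other cells differed by -0.89 for Lyz2, -2.73 for C1qb, -2.76 for C1qc, -1.42 for Tnnt2, -1.31 for Egfl7, -1.72 for Mcam, -2.31 for Notch3, -1.52 for Lrrn4, -1.46 for Upk3b and -1.80 for Cnp. The rest were Lbh -0.68, Idi1 -1.13, Mvk -1.84, Slc40a1 -0.88, Prmt1 -0.85, Ndufb10 -0.99, Ncoa2 -0.44, Olfml1 -5.25, Heyl -4.48, Dkk2 -4.94, Pdlim3 -5.17 and Gas1 -5.64.

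Among these genes, the difference for Meox1 lost its call without vehicle 4 h replicate 1 (adjusted p = 0.0604), treated 4 h replicate 1 or 2 (0.0562 and 0.0893), vehicle 24 h replicate 1 or 2 (0.0599 and 0.0862) and treated 24 h replicate 2 or 3 (0.098 and 0.118), with edgeR each time. It also lost it with DESeq2 (0.0587) and FPKM values (0.764). Without vehicle 4 h replicate 1, Lbh lost its call (0.0525), without vehicle 4 h replicate 2, Mt3 (0.898) and Trim54 (0.99985), and without treated 4 h replicate 1, Olfml1 (0.0826). Without a filter Aspn (0.0711) and Ndufb10 (0.0669) were not called, nor was Ncoa3 with library totals (0.0502).

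List medians of the difference were 0.41 for NRF2 targets, 1.08 for ATF4 and the integrated stress response, 0.22 for ER chaperones, 1.23 for heat shock, 1.26 for the proteasome and 0.57 for immediate early genes. They were -1.35 for matrix, -0.64 for the myofibroblast response, -0.49 for inflammatory genes, -2.41 for interferon, -2.23 for the cell cycle, -0.73 for cholesterol synthesis, -0.84 for fibroblast identity, -0.90 for leukocytes and -1.27 for pericytes and smooth muscle (camera adjusted p from 3.9e-22 to 0.0335). With an estimated correlation the smallest adjusted p of these camera tests was 0.0652.

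At 24 h 11628 genes were called, against 1098 at 4 h. A smaller spread between the 24 h libraries as the whole cause is argued against by a fit with one spread for all 12 libraries, which left a ratio of the counts of 5.11. That fit called 2198 genes at 4 h and 11230 at 24 h, so the contrast shrank. It also estimates the spread from more libraries, so how much of the shrinkage is due to unequal spread cannot be told. Length or GC trends of single libraries as the whole cause are argued against by a ratio of 6.44 after their removal. Removal took the limma counts from 1105 to 1782 at 4 h and from 11548 to 11479 at 24 h. What stays open is different cultures or handling at the 2 times, since 8066 of 15594 genes differed between the vehicle libraries of the times, ribosomal RNA made up 0.543 to 1.10% of the counts in the 4 h libraries and 2.27 to 4.09% in the 24 h ones, the names of the 24 h group means carry a prefix that the labels do not explain, and no library separates time from culture, so this cannot be told apart from the longer exposure. Among the 10 splits of the 6 libraries at 4 h, 1 gave as many genes, the real one, and the highest other called 1; at 24 h 1 of 10 did, and the highest other called 0; 10 splits are too few for a share under 0.05. Of 100 splits drawn for the difference between times (8796 genes), 5 gave as many, the real one included, up to 9267, but all 5 kept the real 24 h grouping and so carried the 24 h response, while the 91 splits without that grouping called at most 1, so that the count follows this grouping and says nothing about chance.

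Interferon genes were lower at 24 h (28 of 29), with 0 called at 4 h. One vehicle library with a high level is argued against, since at least 27 interferon genes stayed lower without any 1 library. Less leukocyte RNA in the treated cultures stays open as a whole or partial cause: per library, the interferon median minus the leukocyte median differed by -0.98 between treated and vehicle libraries, and the exact permutation p over the 6 libraries was 0.1, the smallest that 3 against 3 can give. The leukocyte genes ran from C1qb at -3.32 to Csf1r at 0.22 and Cd14 at 1.09, and which of them the fibroblasts also express was not tested. The list lay 1.34 higher in the 24 h than in the 4 h vehicle libraries, so for the difference between the times a longer exposure and a raised vehicle level cannot be told apart, because the times differ in culture.

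Vehicle 4 h replicate 1 lay apart from the other 4 h vehicle libraries, with 77 genes more than 2-fold below both. With each library's length and GC trend removed the count was 44, and whether these were among the 77 was not tested. Such a trend may account for part of the difference, and it cannot be told apart from a difference between cultures, because the labels do not give their origin. Across genes, its deviation from the mean of the other 4 h vehicle libraries correlated with GC content (Spearman's rho -0.48). Treated 4 h replicate 1 had nearly the same value against its own group (-0.42), with 0 genes more than 2-fold below both others. The remaining 4 h libraries ranged from 0.18 to 0.40, and vehicle replicates 2 and 3 were themselves compared with a mean that includes replicate 1. No biological explanation was tested, since replicates have no group of their own.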

How the results depend on the processing

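Fits without ribosomal RNA genes and without the 100 most abundant genes were chosen after seeing the data. Most genes of the naming rule were picked for large changes in these same data, and alternatives under which a gene was not tested were left out. Their tally therefore says little about calls of smaller changes. Of the 213 results of genes picked by the naming rule, 3688 values under the alternatives kept direction and side of the threshold, 67 lost the call, 1 gained it (Ncoa3 at 4 h) and 4 changed sign. For the 44 results of the lists other than NRF2 targets these were 359, 28, 8 and 1. Of the 28 losses, 6 at 4 h and 15 at 24 h came from camera with an estimated correlation, under which no list was called at 24 h. Fry lost 2 calls at 4 h, kept the other calls of both times, and gained ER chaperones at 4 h (fry adjusted p = 0.0487). At 24 h fry gained 4 lists: metal response (7 genes, 4.7e-05), Schwann cells (3 genes, 0.000221), cardiomyocytes (2 genes, 0.0232) and epicardium and mesothelium (6 genes, 0.0386). The count of 1098 genes at 4 h became 1953 with the replicate number as a block, 701 with limma-trend on FPKM, 2198 with all 12 libraries in one fit and 200 with a log2 fold change of at least 1, and ranged from 443 (without treated replicate 3) to 1760 (without vehicle replicate 1). The minimum fold removes genes by construction, and for the others the cause was not tested. The labels do not state that replicates are paired: at 4 h deviations of same-numbered libraries correlated with r of 0.0879, 0.0832 and 0.109, at 24 h with 0.0133, 0.0200 and -0.0430. Between libraries of unlike number r ran from -0.108 to 0.0196 at 4 h, below all same-numbered values. At 24 h it ran from -0.0799 to 0.0717, around the same-numbered ones. Whether same-numbered libraries are paired at 4 h therefore stays open, and the main count there ignores such a pairing. With that fold minimum, the counts were 4908 at 24 h, 3838 for the difference and 166 for the shared direction (988 without it), which was not computed under other settings. Under the others the count stayed from 9290 to 12427 at 24 h and from 7276 to 9120 for the difference. The NRF2 list at 24 h lost its call with an estimated correlation (camera adjusted p = 0.1155), and without any 1 library ranged from 1.7e-11 to 4.84e-11. At 4 h Ncoa2, not called (-0.01), changed sign with FPKM values (0.0061) and ranged from -0.0497 (without vehicle replicate 2) to 0.0152 (without vehicle replicate 1). The interferon list at 4 h ranged from adjusted p = 9.87e-05 (lower, without treated replicate 3) to 0.813 (without vehicle replicate 2), and turned upward without treated replicate 2 (0.000134); the cause was not tested. Other pseudocounts and scalings of FPKM were not run, since counts were given. Of simulated changes of 1.5-fold, 36.7% were recovered at 4 h and 63.3% at 24 h. Far fewer genes changed there than were called in the data, so these shares do not measure how many small changes were missed.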

Other observations

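Gene families formed by shared symbol stems, with at least 8 protein-coding members, were tested with camera after seeing the data, 231 at 4 h and 230 at 24 h. Of these 4 were called at 4 h and 26 at 24 h, and with an estimated correlation the smallest adjusted p was 0.779, so that no family passed there. The medians kept their sign with RLE factors, library totals, FPKM values, DESeq2, no filter and an FPKM minimum. Of these, only library totals drop the scaling between libraries, since the FPKM values carry one close to TMM. Of 9 frizzled (Fzd) receptor genes 3 fell at 4 h and the others were not called (median -0.30, camera adjusted p = 0.00389, but adjusted p = 0.942 with an estimated correlation, Fzd4 at -1.15), and at 24 h most were lower (8 fell and 1 rose, median -1.28, adjusted p = 0.0299, Fzd2 and Fzd4 at -2.64). At 24 h, 13 of 14 Adamts protease genes fell (median -1.92, camera adjusted p = 0.00256), with Adamts15 at -5.31 and Adamts5 at -3.21, and 9 of 10 Chst sulfotransferase genes fell and 1 rose (median -1.56, adjusted p = 0.0464). Autophagy (Atg) genes rose in 14 of 17 cases and fell in 2 (median 0.64, camera adjusted p = 0.00996), with Atg14 at 2.29 and Atg12 at 1.78. Of 50 genes with the stem Rpl of ribosomal proteins, 40 rose and 0 fell (median 0.43, camera adjusted p = 2.8e-05), but 30 rose and 3 fell when scaled by library totals (median 0.23). They include Rpl10-ps3 and Rpl9-ps6, whose symbols mark pseudogene copies, and reads shared with such copies make these values uncertain.

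Between the vehicle libraries of the times, edgeR called 8066 of 15594 genes, 4039 higher and 4027 lower at 24 h. List medians, 24 h minus 4 h vehicle, were 1.99 for leukocytes, 1.34 for interferon, 1.15 for Schwann cells, 1.02 for the cell cycle (38 of 38 genes higher), 0.39 for oxidative phosphorylation and 0.33 for endothelium. They were -0.53 for ATF4, -0.62 for metal response, -1.09 for immediate early genes (28 of 33 lower), -1.17 for pericytes and smooth muscle, -1.60 for epicardium and mesothelium and -1.73 for cardiomyocytes. The other 11 lists ran from -0.49 to 0.28. Set against the 4 h vehicle libraries, the treated 24 h libraries had medians of 2.16 for heat shock, 1.66 for the proteasome, 1.64 for NRF2, 1.06 for ATF4, -1.50 for the cell cycle, -1.15 for matrix and -0.84 for interferon, in the direction of the 24 h response. Medians of the opposite sign to that response were -0.50 for immediate early genes, -0.20 for metal response, 0.47 for leukocytes and -0.68 for cardiomyocytes, and that of p53 targets was 0.06. Here the cardiomyocyte and leukocyte medians cover 5 and 15 genes, against 2 and 13 in the 24 h response, so their signs compare unlike sets. These values across times were not separated from separate handling of the cultures.

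Some shares of the counts separated the treated from the vehicle libraries, which chance gives in 10% of cases for 3 against 3. At 4 h ribosomal RNA made up 0.543 to 0.900% of the counts in vehicle and 0.949 to 1.10% in treated libraries, whereas at 24 h the ranges overlapped (2.92 to 4.09% and 2.27 to 3.90%). At 24 h pseudogenes made up 0.695 to 0.708% in vehicle and 0.806 to 0.826% in treated libraries, and the 10 most abundant genes 7.71 to 8.81% and 9.41 to 10.7%. At 4 h both of these ranges overlapped.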
